A study of Passiflora edulis with 2 samples.

How the data were processed

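RNA of seedling leaves was sequenced as paired reads from poly(A)-selected libraries on an Illumina NovaSeq instrument, per the labels' protocols. Groups were taken from the sample labels, with 1 library of the solvent control (CK) and 1 library of the agent-treated group (COS), both labelled replicate 2. The submitters' processing notes name cutadapt, FastQC, Salmon and edgeR, without versions, roles or settings. The deposited table gives assembled genes with identifiers of the Trinity assembler, their length of 201 to 12271 nt, and functional annotation. No genome build or coordinates are given, so genes are named by their identifier (shortened here by its TRINITY prefix) and by the symbol or description of the annotation. Whether replicates were pooled and which strand was counted are not given in the sources used here, so antisense and overlapping transcripts cannot be told apart from their partners.

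The authors deposited expected counts, per the file headers, which are estimated reads per gene and need not be whole: 92.7% of the CK values and 93.0% of the COS values were. They also deposited a second pair of columns named only by group. From the values these deposited columns are TPM, a length-normalised share of transcripts, since each sums to nearly the total that unit has (998603 and 998611) and the value per count falls with gene length. The expected counts were used for the reported results and the TPM values for an alternative. Of the 39948 genes in the table, 13236 had no Nr annotation and 20636 no Swiss-Prot annotation. No row lacked a gene name, and 0 columns belonged to other samples.

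Expected counts were scaled to counts per 1e6 counts of the library total (CPM). The log2 ratio was log2 of (COS + 1) over (CK + 1), which understates the difference of genes with few counts, where 1 is the pseudocount in CPM. Genes with at least 10 counts in either library were kept, which left out 12497, and genes at least 2-fold apart were counted. With 1 library per group no test was run. Because the median log2 ratio of genes with at least 10 CPM in both libraries was -0.28, which is beyond 0.1, ratios are reported relative to it. The pseudocount was added before this centring, so on the relative scale genes with few counts are drawn to a value above 0. Named genes have exact (Clopper-Pearson) 95% intervals of their count ratio, and shares of counts have exact 95% intervals. A count of 0 was bounded by a floor of 3 counts, which is 0.138 CPM in CK and 0.129 CPM in COS. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and not the variation between plants.

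Before the data were examined, 36 gene lists were fixed as text patterns for defence, hormones, photosynthesis, growth, other tissues, organelles and viruses, and matched to the annotation columns, where 3127 genes matched at least 1 list. Each list was described by its median with a binomial 95% interval and by the percentile of that median among 10000 random lists of the same size matched on mean log2 level in 20 bins (seed 1). The percentile describes these libraries and is not a test of the treatment. The middle 95% of random lists (percentiles 2.5 to 97.5) was chosen as the band for a list to stand apart after the data were seen. So were the preference for the Swiss-Prot description, the grouping of viral genes by virus, and the split of potyvirus-like genes at 50 times the CK count.

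The genes named follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among the 12959 annotated genes with at least 100 counts in the higher library, with 1 gene per annotation text, the 2 highest and 2 lowest members of each list with at least 10 CPM, the viral genes with at least 1 CPM, summarised where there are over 10, and the 5 most abundant genes. Fewer than the rule allows are printed, and genes outside it are marked as named after their values were seen.

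The procedure was tested on simulated data for the comparison of CK with COS over 27451 genes. Changed genes were drawn only from those whose mean level equals at least 100 counts in the smaller library, and calls used the ratio without centring. Of 100 such genes with a simulated 3-fold change 99% were recovered at 2-fold, and of 100 with a 4-fold change 100%. Recovery of genes nearer the filter of 10 counts was not simulated. The exact interval held the simulated fold for 98% of 200 changed genes, and 6 of 100 random lists of 50 genes fell outside the middle 95%. The alternatives tried were other pseudocounts, filters, thresholds and scalings, edgeR's trimmed mean of M values (TMM) factors on counts rounded to whole numbers, 1 gene per annotation text and, added after seeing the data, the TPM values, CPM of non-viral counts, and removal of the viral genes. KEGG pathways with at least 10 genes were described in the same way as the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with edgeR 4.0.16 in R 4.3.3 for the TMM factors.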

Results

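Leaves of passion fruit (Passiflora edulis) seedlings were profiled by sequencing of poly(A)-selected RNA in 2 libraries. The CK library came from control seedlings given solvent without compound, and the COS library from seedlings given a 5% amino-oligosaccharide agent. The series title places the work in the control of a virus infection abbreviated CMV, read here as cucumber mosaic virus. The labels used here do not say whether or when the seedlings were inoculated. Each group holds 1 library, so no difference has a replicate check, no test of the treatment was possible and no p-value is given. The CK library held 21669472 expected counts and the COS library 23338520, over 39948 assembled genes, of which 27451 had at least 10 counts in either library. Across the 27394 of these outside the viral list, log2 levels of the 2 libraries had a Pearson correlation of 0.979 and a Spearman correlation of 0.966. These correlations are across genes, which are not independent replicates.

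The first question was which viral RNAs the leaves of each group contained. Genes annotated as potyvirus polyproteins, which come from a genus of plant viruses with a polyadenylated RNA genome, made up 15.1% of the CK counts and 35.1% of the COS counts. The higher share in the COS library came from 4 assembled genes that took 0.0162% of the CK counts and 22.0% of the COS counts, 1357 times the CK share (exact 95% interval 1312 to 1403). The longest of these, DN16337_c2_g1 at 10014 nt, had 316 counts in CK and 445679 in COS. DN16426_c1_g3, at 9495 nt, had 2882 counts in CK and 4652089 in COS, which made it the most abundant gene of the COS library at 19.9% of its counts. The shorter DN11055_c0_g5 had 291 counts in CK and 27167 in COS, and DN11716_c0_g4 had 24.0 and 7748. The best Swiss-Prot match of all 4 was soybean mosaic virus, which names the nearest entry of that database and not the virus species in the leaves.

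A further 17 potyvirus-like genes, of which 13 matched soybean mosaic virus and 4 bean common mosaic necrosis virus, were present in both libraries, at 15.04% of the CK counts and 13.1% of the COS counts. Their COS share was between 0.459 and 1.38 times their CK share. Per 1e6 non-viral counts the 17 genes together had 177380 in CK and 202633 in COS, 1.14 times as high. The direction thus depends on the scale, since the 4 genes abundant in COS lower every other share of that library. The most abundant gene of the CK library was among the 17: DN16627_c2_g1, at 6953 nt, had 2258412 counts in CK and 2300360 in COS. Another, DN13738_c0_g1, with a bean common mosaic necrosis virus match, had 667201 counts in CK and 438591 in COS. A further set of 10 genes matched turnip mosaic virus and had 1362 counts in CK and 0 in COS. Against a floor of 3 counts its CK share was 489-fold higher, and the exact interval of its COS over CK ratio reached up to 0.00252.

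Other viral annotations held few counts. A carlavirus-like replication polyprotein gene of 8345 nt, DN16504_c1_g3, had 41 counts in CK and 816 in COS, a share 18.5 times as high (exact interval 13.5 to 25.9). The 17 caulimovirid-like genes, a DNA virus family that also leaves inserted copies in plant genomes, had 35621 counts in CK and 6081 in COS, 6.31-fold higher in CK. The bulk of that came from DN16572_c0_g1, an enzymatic polyprotein with 20877 counts in CK and 98.8 in COS, and DN16572_c0_g3, a putative movement protein with 5797 and 23.2. DN14811_c0_g2, a genome polyprotein, had 1202 and 3 counts. DN11489_c1_g3, with most of the COS counts of the set, had 5502 and 5123, and DN14348_c0_g3 had 13 and 25. Maculavirus-like genes had 29 counts in CK and 47 in COS, genes matched to animal virus entries had 660 and 737, and a begomovirus-like gene had 0 in both. The remaining match of the viral pattern was a clathrin light chain gene of the plant, with 964 counts in CK and 856 in COS. No gene was annotated as a cucumovirus, the genus of cucumber mosaic virus (0 of the 39948 genes). Genomic RNAs of cucumber mosaic virus carry no poly(A) tail, so poly(A) selection does not target them. Reads of a virus with no assembled gene, or in a gene without annotation, would not be counted under its name, so the share of such RNA has no limit here.

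**Figure D1:**
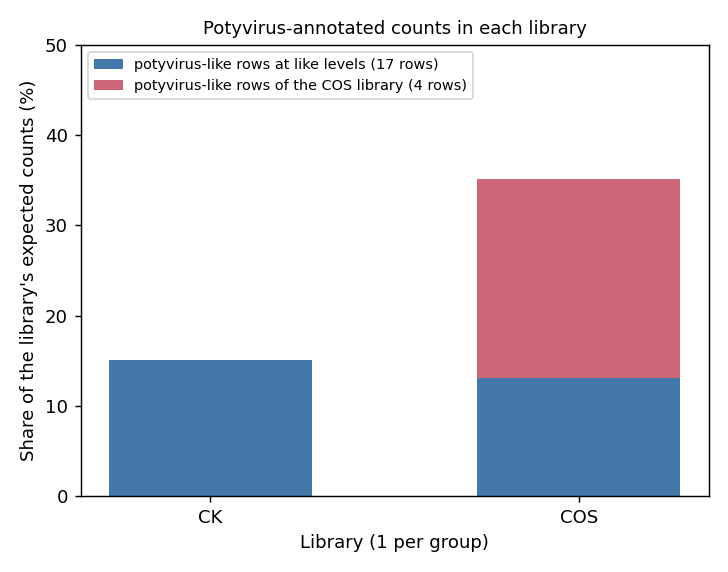
Share of each library's expected counts (percent, vertical axis) taken by potyvirus-like genes in the CK and COS libraries, 1 library per bar. The 17 genes present in both libraries (blue) took 15.04% in CK and 13.1% in COS, and the 4 genes abundant in COS (red) took 22.0% of the COS counts and 0.0162% of the CK counts, too little to be seen as a red part of that bar. The exact intervals are narrower than the line width and are not drawn.

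The second question was which plant genes differed between the libraries. The list of cell wall loosening genes had a median above those of random lists, and the lists of proteinase inhibitors and of the Calvin cycle had medians below the middle 95% of them, while 96.5% of genes lay within 2-fold of the median gene. The median of the 11591 genes with at least 10 CPM in both libraries lay at a log2 ratio of -0.28, COS over CK, on the library-total scale. In CPM of non-viral counts the median of the same genes was 0.09. Values below are log2 ratios relative to the median gene of the library-total scale unless said otherwise. On this scale 655 genes were at least 2-fold higher in COS and 301 at least 2-fold lower, so that 68.5% of them were higher. On the library-total scale the counts were 307 higher and 723 lower, or 29.8% higher, so the balance of directions depends on the scaling. With TMM factors, which scale before the pseudocount is added, the median of the same genes was 0.003. The counts were then 516 higher and 351 lower, or 59.5% higher. Centring after the pseudocount thus favours higher calls. A gene with 1 count in CK and 17 in COS was called higher, at 1.01, while 1 with 27 and 0 was not called lower, at -0.88. At least 4-fold apart were 66 higher and 42 lower genes relative to the median gene, and 32 higher and 63 lower on the library-total scale. Counting noise alone gave 0 calls, on the ratio without centring, among 25791 unchanged genes in simulated libraries of these sizes. Calls on the centred ratio were not simulated, so this does not cover the 655 and 301 genes. Differences between plants of 1 group were not measured.

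Among annotated plant genes with at least 100 counts, the highest log2 ratio with the pseudocount of 1 CPM was that of polygalacturonase At1g48100 (DN12988_c0_g1), a pectin-degrading enzyme, at 3.67, or 1.92 with the deposited TPM values (8.14 and 34.9). Its counts were 71.1 in CK and 1022 in COS, a ratio of 16.2 relative to the median gene (exact interval 12.8 to 21.0). GDSL esterase/lipase At5g33370 (DN12206_c1_g1) followed at 3.62 with 7 and 288 counts, and its ratio without a pseudocount, relative to the median gene, was higher, 46.5 (22.3 to 117). The gibberellin-responsive type gene GAST1 (DN10514_c0_g2) was at 3.27 with 282 and 2562 counts, a ratio of 10.3 (9.08 to 11.7). EXPB3, an expansin that loosens cell walls, was at 3.09 with 30 and 366 counts, ABIL5 at 3.04, the aspartic proteinase nepenthesin-1 at 2.99, EPFL2, a member of the epidermal patterning factor peptides, at 2.84, and beta-glucosidase BGLU12 at 2.70 with 854 and 4994 counts.

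The lowest plant genes included several that were nearly or fully undetected in the COS library. A gene annotated as GDSL esterase/lipase At1g29670, DN11741_c1_g6, had 1248 counts in CK and 1 in COS, while DN13013_c0_g7, with the same annotation, had 14 in CK and 283 in COS. Desiccation-related protein PCC13-62 (DN14554_c2_g8) had 288 counts in CK and 0 in COS, 103-fold lower against the floor of 3 counts on the library-total scale. A hydroxynitrile lyase (DN11331_c1_g1) had 172 and 0, 61.7-fold lower. The exact intervals of their COS over CK ratios on that scale reached up to 0.0120 and 0.0201. Beta-amyrin synthase, an enzyme of triterpene synthesis, was at -3.42 with 334 and 6 counts. CCD4, a carotenoid cleavage dioxygenase, was at -3.13 with 2822 and 263 counts. The WAT1-related gene At5g07050 was at -3.03, a Tf2-12 transposon polyprotein at -2.73 with 1636 and 197 counts, and nicotianamine synthase, which makes a metal chelator, at -2.71 with 447 and 40 counts. Assembled genes can be alleles or fragments of 1 locus, and reads shared between close copies can be split among them, so single genes of multigene families are uncertain.

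**Figure D2:**
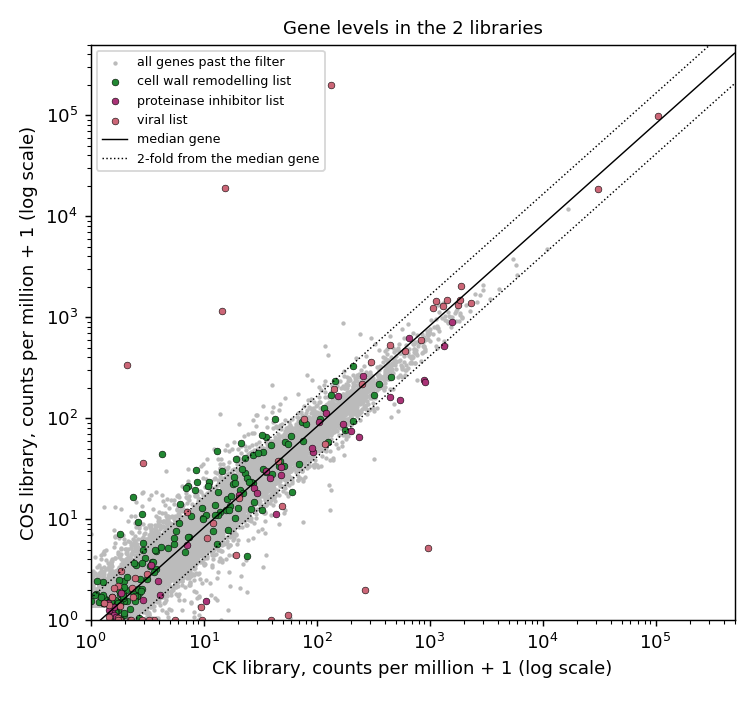
CPM plus 1 of each of the 27451 genes past the filter in the CK library (horizontal, log axis) and the COS library (vertical, log axis). The solid line marks the median gene and the dotted lines 2-fold above and below it. Of the 167 cell wall genes (green), 25 lay at least 2-fold above the median gene, and of the 37 proteinase inhibitor genes (purple), 9 lay at least 2-fold below it. The viral list (red) holds the points farthest from the line.

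Cell wall loosening and remodelling genes had the highest median of the 36 gene lists, at 0.32 (95% interval of the median 0.16 to 0.40). It lay above the medians of the 10000 random lists matched on mean expression (percentile 100). Of its 167 members, 25 were at least 2-fold higher in COS, 4 at least 2-fold lower and 112 lay above the median gene. On the library-total scale it was the only list with a median above 0, at 0.038, with 20 members higher and 10 lower. Beside At1g48100 and EXPB3, members named after their values were seen were XTH9 (DN10500_c0_g3), a xyloglucan-modifying enzyme, at 2.15 with 261 and 1085 counts, expansins EXPA5 at 1.81, EXPA2 at 1.69, EXPA8 at 1.47 and EXPA10 at 1.34, pectinesterase PME54 at 1.70, and pectate lyase 8 (DN13991_c0_g2) at 1.84. Members in the other direction were EXPA1 at -2.21 with 502 and 77 counts and XTH30 at -1.41 with 1289 and 413.

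Proteinase inhibitors, proteins that block digestive proteases of feeding insects and pathogens, had the lowest median, -0.36 (-0.57 to -0.07, percentile 0), with 0 of 37 members at least 2-fold higher and 9 at least 2-fold lower. They took 0.958% of the non-viral counts in CK and 0.608% in COS. Among the 9, 8 carried the same annotation of a partial miraculin-like protein, a relative of Kunitz inhibitors. DN11728_c0_g2 had 19722 counts in CK and 5345 in COS, at -1.70. The ninth was Kunitz trypsin inhibitor KTI2 at -1.68 with 932 and 239 counts. Multicystatin lay at 0.30.

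The Calvin cycle list had a median of -0.21 (-0.42 to -0.06, percentile 0.06), with 4 of 30 members at least 2-fold lower and 0 higher. A Rubisco small subunit gene, RBCS (DN12605_c0_g1), was at -1.37 with 1612 and 536 counts, and GAPB, the plastid glyceraldehyde-3-phosphate dehydrogenase, at -1.04. The most abundant plant gene, another RBCS gene (DN11793_c0_g1), took 361991 counts in CK and 276931 in COS and lay at -0.21. Photosystem and light-harvesting genes had a median of -0.11 (-0.20 to -0.03, percentile 0.32), with 65 of 107 below the median gene but 3 at least 2-fold higher and 1 lower. Its lowest members with at least 10 CPM were LHCA3 at -0.71 and PSAN at -0.66. CAB16, a chlorophyll-binding protein of this list, lay the other way at 2.63 with 3723 and 20539 counts. Chlorophyll synthesis genes had a median inside the middle 95% of random lists, -0.16 (percentile 5.23), with 0 of 20 at least 2-fold higher and 1 lower: CAO, which makes chlorophyll b, at -1.08. With a pseudocount of 5 the median of the photosystem list was 0.074 and its percentile 47.6, and with 1 gene kept per annotation text the percentile was 6.56, so its place outside random lists depends on these choices.

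Defence lists held members in both directions. Pathogenesis-related proteins had a median of 0.09 (-0.06 to 0.24, percentile 98.0), or -0.19 on the library-total scale. Of 116 members 5 were at least 2-fold lower and 2 higher (11 and 1 on that scale). The list took 1.48% of the non-viral counts in CK and 1.29% in COS. A thaumatin-like protein gene was at 2.39 with 422 and 2027 counts, while an osmotin-like gene was at -1.57 and MLP34 at -1.67. Pattern-recognition receptors, which sense chitin and other microbial molecules at the cell surface, had a median of 0.23 (-0.03 to 0.37, percentile 99.6), or -0.051 on the library-total scale, over 48 members. Xa21-type receptor kinase XA21 was at 1.09 with 2359 and 4459 counts and the LysM receptor kinase LYK3 at 0.88, while an FLS2-annotated receptor was at -0.59. The percentile was 96.2 for receptors with the deposited TPM values and 95.9 for pathogenesis-related proteins with a pseudocount of 0.1. NLR disease resistance proteins, the intracellular immune receptors, had a median of 0.09 (percentile 56.5), with 4 of 214 at least 2-fold higher and 1 lower (2 and 3 on the library-total scale). RNA silencing genes had a median of 0.09 (percentile 82.1), with 2 of 54 at least 2-fold higher and 0 lower: DRB3, a double-stranded RNA-binding protein, at 1.61 with 78 and 246 counts, and AGO7, an argonaute named after its value was seen, at 2.51 with 28.0 and 227 counts.

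Flavonoid synthesis genes had a median of 0.19 (0.04 to 0.38, percentile 99.9), or -0.091 on the library-total scale, with 4 of 71 at least 2-fold higher and 0 lower (3 and 3 on that scale), among them DMR6 at 1.65 with 1966 and 5510 counts and CHI3 at 1.28. DMR6 is known as an oxygenase that acts on salicylic acid. Phenylpropanoid and lignin synthesis genes had a median of 0.17 (0.04 to 0.25, percentile 99.9), or -0.12 on the library-total scale, with 5 of 90 at least 2-fold higher and 6 lower. The lignin enzymes 4CL1 at 1.09 and CAD6 at -1.15 with 1300 and 504 counts show both directions. Restricted to genes with at least 100 counts, the percentiles were 92.1 for flavonoid and 84.5 for phenylpropanoid genes.

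Hormone lists had medians inside the middle 95% of random lists, with single members far from the median gene. Jasmonate synthesis and signalling had a median of 0.09 (percentile 94.5), with 3 of 53 at least 2-fold higher and 0 lower, among them the repressor genes TIFY3B at 1.86 and TIFY10A at 1.72. Its percentile was 98.1 without a filter on low counts. Salicylic acid genes had a median of 0.04 (percentile 61.4), with 4 of 54 higher and 1 lower (1 and 1 on the library-total scale). NIM1-INTERACTING 1, a partner of the salicylic acid receptor NPR1, was at 2.01 with 81 and 343 counts. Auxin response genes had a median of 0.05 (percentile 80.4), with 14 of 143 higher and 3 lower (7 and 6 on that scale): the auxin-binding germin-like gene ABP19A was at 2.41 with 2561 and 12076 counts, IAA18 at 1.84 and SAUR36 at -1.31. Ethylene genes had a median of 0.01 (percentile 31.0), with 5 of 130 higher and 3 lower (4 and 6 on that scale), among them SHN2, a regulator of cuticle synthesis, at 2.08. Abscisic acid and dehydration genes had a median of 0.04 (percentile 63.6), with 2 of 74 higher and 2 lower (1 and 5 on that scale): LEA5-D was at -1.86 with 11348 and 2740 counts, and of the abscisic acid 8'-hydroxylases, which break down the hormone, CYP707A4 was at -1.40 and CYP707A2 at 1.02.

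WRKY transcription factors, many of which act in defence, had a median of 0.03 (percentile 48.6), with 6 of 72 at least 2-fold higher and 0 lower. WRKY71 was at 1.88 with 90 and 339 counts and WRKY18 at 1.47 with 862 and 2143, and, named after their values were seen, WRKY40 was at 1.44 and a pair of WRKY70 genes at 1.23 and 1.09. NAC factors had a median of 0.04 (percentile 51.1), with 0 of 66 higher and 2 lower, among them NAC056 at -1.15. Reactive oxygen genes had a median of -0.01 (percentile 38.0), with 7 of 137 higher and 3 lower (3 and 10 on the library-total scale), among them the iron superoxide dismutase FSD1 at -1.11 with 30511 and 12495 counts. Calcium signalling genes had a median of 0.04 (percentile 86.2), with CNGC4, a cyclic nucleotide-gated channel, at -1.32 with 3301 and 1155 counts and CRLK1 at 1.27. MAP kinase cascade genes had a median of 0.05 (percentile 65.4) and 0 of 54 members at least 2-fold away.

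Among the metabolic lists, nitrogen assimilation had a median of -0.13 (-0.22 to 0.04, percentile 0.07), with 3 of 66 at least 2-fold higher and 3 lower (2 and 8 on the library-total scale). An asparagine synthetase gene was at 1.60 with 445 and 1230 counts and the transporter NPF4.6 at -1.02. Without a filter on low counts its median was 0.040 and its percentile 3.53. Sugar transport and starch genes had a median of -0.01 (percentile 21.0), with beta-amylase BMY1 at 1.33 and BAM1, a plastid beta-amylase, at -1.23 with 3626 and 1348 counts. Terpenoid synthesis had a median of 0.11 (percentile 96.3), with 3 of 37 higher and 1 lower: TKT2, annotated as a deoxyxylulose phosphate synthase, was at 1.42 with 339 and 833 counts and a germacrene D synthase at -1.09. Senescence genes had a median of 0.04 (percentile 70.6) over 16 members, 0 of them higher and 1 lower: DIN1 at -2.48 with 2869 and 436 counts. Cytosolic ribosomal proteins had a median of 0.06 (0.02 to 0.09, percentile 99.8), or -0.22 on the library-total scale, and the percentile was 64.8 with a pseudocount of 5 and 0.02 without a filter on low counts. Plastid and organelle ribosomal proteins had a median of -0.01 (percentile 48.4), heat shock proteins 0.00 (percentile 26.9), cell cycle and histone genes 0.02 (percentile 28.4) and housekeeping genes 0.01 (percentile 54.4).

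Lists that mark other tissues, organelles or the time of day gave these values. Root and vascular markers had a median of 0.14 (percentile 93.8), with 3 of 37 at least 2-fold higher and 0 lower, among them the fasciclin-like arabinogalactan genes FLA13 at 2.14 and FLA17 at 1.35. Flower and meristem markers had a median of 0.01 (percentile 29.8). Organelle-encoded transcripts had a median of -0.03 (percentile 1.98), which was 85.6 for genes with at least 100 counts. Circadian clock genes had a median of -0.04 (percentile 22.0) and 0 of 34 members at least 2-fold away: the morning gene CCA1 was at -0.93, APRR5 at -0.83 and the evening-type gene EFL1 at 0.90. The viral list had a median of -0.05 (percentile 17.3), since most of its members are not the abundant genes described above. The list for non-plant organisms had a median of 0.01 (percentile 7.94), and 0 of its 1076 matches named a species of the list in the Nr description.

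Of the 36 lists, 6 had a median above and 5 below the middle 95% of random lists, where independent genes and lists would give 0.9 per side. Some lists share genes and some hold several genes of the same annotation, so 0.9 is not the number to be had from chance here. Median and mean had opposite signs in the NAC (mean -0.02), reactive oxygen (mean 0.06), senescence (mean -0.14), plastid ribosomal (mean 0.00) and viral (mean 0.05) lists.

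**Figure D3:**
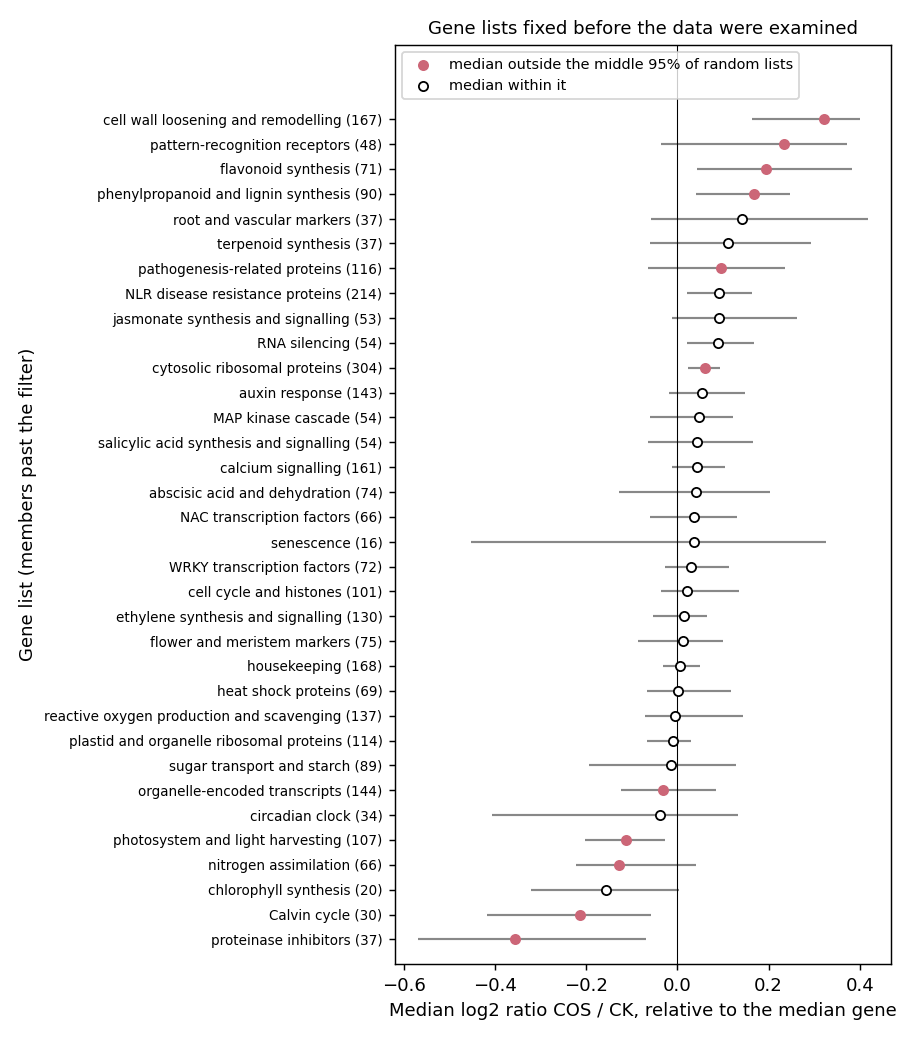
Median log2 ratio of COS over CK relative to the median gene (horizontal axis) for 34 gene lists, with the number of members past the filter in brackets. Points are medians, lines are binomial 95% intervals of the median over genes, and filled points have medians outside the middle 95% of 10000 random lists. Cell wall genes stand highest at 0.32 and proteinase inhibitors lowest at -0.36, and on the library-total scale every point lies lower by the shift of the median gene.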

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

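The settings TPM, non-viral counts and removal of viral genes, and the use of TMM for lists, were chosen after seeing the data. Cell wall, Calvin cycle and proteinase inhibitor lists kept their place outside the middle 95% of random lists under the 10 alternatives run for each: percentiles were 100 for cell wall genes, 0.01 to 1.04 for the Calvin cycle, and 0 to 0.01 for proteinase inhibitors. Over the lists together, 329 of the list percentiles under an alternative kept their call, 14 lost it, 14 gained one and 2 crossed the middle of the random lists. Of these 2, cytosolic ribosomal proteins came to lie outside the band on its other side and organelle-encoded transcripts inside it. Of the values of named genes under an alternative, 920 stayed within their counting interval, 221 moved beyond it, and 0 of those at least 2-fold apart changed sign. List and named-gene values were already centred, so the alternative centred on the median gene repeated them by construction. Its part of the 10 alternatives, of the 329 kept calls and of the 920 values is no check. Centring adds the same amount to every log2 ratio and so moves the 2-fold boundary. Under it the 307 genes called higher on the library-total scale were all still called, and 301 of the 723 lower ones. That all 307 stayed was fixed by construction and is no check of the calls.

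Centred on the median gene, the main scale of the results, 655 genes were at least 2-fold higher and 301 lower in COS. On the library-total scale the counts were 307 and 723. On that scale they were 1328 and 3054 with a pseudocount of 0.1, and 102 and 268 with a pseudocount of 5. Raising or lowering the threshold on it gave 32 and 63 at 4-fold and 1021 and 3828 at 1.5-fold. With TMM factors the counts were 516 and 351, and in CPM of non-viral counts 761 and 394. With TPM of at least 1 in either library they were 3380 and 2826. The pseudocount sets how far the ratios of genes with few counts are drawn to 0 or, where centring follows it, to a value above 0. The scaling sets the centre. The cause of the TPM counts was not tested.

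For the lists below the cause was not tested. With a pseudocount of 0.1 the percentile was 95.9 for pathogenesis-related proteins and 97.7 for terpenoid synthesis. With a pseudocount of 5 it was 47.6 for photosystem genes (median 0.074), 64.8 for cytosolic ribosomal proteins, 9.70 for organelle-encoded transcripts (median 0.11) and 1.12 for non-plant organisms. Without a filter it was 98.1 for jasmonate, 0.02 for cytosolic ribosomal proteins, 3.53 for nitrogen assimilation (median 0.040), 4.17 for organelle-encoded transcripts (median 0.093) and 0 for non-plant organisms. With at least 100 counts it was 97.8 for jasmonate, 84.5 for phenylpropanoid, 92.1 for flavonoid, 0.06 for sugar transport and starch, 99.02 for terpenoid synthesis and 85.6 for organelle-encoded transcripts (median 0.032). With TMM factors it was 96.2 for pathogenesis-related proteins, 97.53 for jasmonate and 98.8 for terpenoid synthesis. With 1 gene per annotation text it was 6.56 for photosystem genes, 2.13 for sugar transport and starch, 0.52 for abscisic acid and dehydration and 10.6 for organelle-encoded transcripts. In CPM of non-viral counts it was 96.4 for pathogenesis-related proteins, 98.4 for jasmonate, 98.9 for terpenoid synthesis and 3.90 for organelle-encoded transcripts. With TPM it was 96.2 for pattern-recognition receptors and 98.5 for calcium signalling. Without centring, medians on the library-total scale were -0.19 for pathogenesis-related proteins, -0.12 for phenylpropanoid, -0.091 for flavonoid, -0.051 for pattern-recognition receptors and -0.22 for cytosolic ribosomal proteins.

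No paired analysis was possible because each group holds 1 library. For the same reason leaving out a library in turn does not apply. Counts of genes past the authors' own threshold were not run, since the table used here has no columns of such a comparison. Depth limits genes near 10 counts, where the pseudocount moves the ratio most. The large share of viral RNA left 18368993 non-viral counts in CK and 15131215 in COS.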

Other observations

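A list of cuticle and wax synthesis genes, drawn up once the KEGG pathway of fatty acid elongation had been seen to be high and sharing 3-ketoacyl-CoA synthase genes with it, had a median of 0.22 (95% interval 0.00 to 0.37) relative to the median gene. That median turns negative on the library-total scale, where the median gene lies at -0.28. Of the 78 members of the list, 12 were at least 2-fold higher in COS and 1 lower, relative to the median gene. Among them were cytochrome P450 86A2, a cutin enzyme (104 counts in CK and 373 in COS, 1.83), the cutin exporter ABC transporter G family member 32 (472 and 1543 counts, 1.84), HOTHEAD (37 and 168 counts, 1.88) and 3-ketoacyl-CoA synthase 11 (237 and 452 counts, 1.06). Genes annotated as the cutin enzyme glycerol-3-phosphate 2-O-acyltransferase 6 went both ways, from 1.81 (DN13301_c0_g4, 611 and 1935 counts) to -1.27 (DN15429_c0_g1, 165 and 45 counts). The KEGG set of cutin, suberine and wax biosynthesis, which was not drawn up from these data, had a median of 0.12 (-0.10 to 0.62) with 8 of 28 genes at least 2-fold higher and 0 lower, and its percentile of 91.1 lay inside the middle 95% of random sets.

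Of 121 KEGG pathways, 15 had a median above and 15 below the middle 95% of random sets, where independent genes and pathways would give 3.02 per side. Indole alkaloid biosynthesis had the highest median, 0.56 over 14 genes, with 2 at least 2-fold higher and 0 lower. Above the band were also pentose and glucuronate interconversions, a pathway that holds the pectin enzymes, at 0.27 (percentile 100, 18 of 134 genes at least 2-fold higher and 1 lower), amino sugar and nucleotide sugar metabolism at 0.12 (percentile 100, but 0 of 172 higher and 3 lower), phenylpropanoid biosynthesis at 0.16 (16 of 182 higher and 6 lower), and fatty acid elongation at 0.19 (percentile 99.8, 1 of 36 higher and 0 lower). Plant-pathogen interaction was at 0.08 (percentile 98.3), with 11 of 338 genes at least 2-fold higher and 3 lower. Below the band were carbon fixation at -0.21 (percentile 0, 0 of 103 higher and 3 lower) and circadian rhythm at -0.08 (percentile 0.27, 0 of 100 higher and 3 lower). RNA transport at -0.07 (percentile 0, 2 of 303 higher and 1 lower) and spliceosome at -0.06 (percentile 0.03, 4 of 286 higher and 1 lower) were below it as well, with 2-fold counts the other way. Positive pathway medians below 0.28 turn negative on the library-total scale.

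All tests below except that of assembled copies were chosen after the result they bear on was seen. Those of read assignment and of leaf stage replaced earlier tests that used genes picked from these data, and their limits were set with the test values already known, so their outcome carries less weight. A test of the scaling factor was dropped because it could not have failed. The 4 potyvirus-like genes abundant in COS were first weighed as reads of the shared potyvirus-like genes assigned to them. Moving reads among the 21 genes with soybean or bean potyvirus matches leaves their sum as it was, and the share of the 21 together was 2.33 times as high in COS as in CK, which argues against such moves as the whole source of the higher share. Reads carried over from the COS library into the CK library were weighed for the CK counts of the genome-length genes. These counts are 0.0709% and 0.0620% of the COS counts, with intervals of 0.0633% to 0.0792% and 0.0597% to 0.0643%. Overlap of separate intervals does not show that the fractions are equal, and they were not compared directly. Carry-over at 1 fixed fraction thus stays open for these counts. It does not by itself account for those of the shorter genes, whose fractions are 0.310% and 1.07%, with a lowest bound of 0.199%. Whether the seedlings sampled for COS differed in infection before the treatment or through it stays open and was not tested, with 1 library per group.

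The higher cell wall and lower Calvin cycle genes in COS were weighed as a difference in time of day and as a difference in leaf stage. A single scaling factor shifts both lists alike, so it does not set the gap between them. On the library-total scale the medians were 0.038 for cell wall and -0.50 for Calvin cycle genes, with the same signs as relative to the median gene. Time of day cannot be told apart from other causes and stays open. Morning clock genes had a median of -0.45 (percentile 0, 10 of 11 below the median gene). Evening clock genes had a median of 0.13 (percentile 91.4, 10 of 15 above the median gene), a difference of 0.58. These directions go with a difference in time of day. The intervals of -0.68 to -0.01 and -0.04 to 0.25 overlap in a narrow range. Such overlap does not show that the medians are alike, and the 2 lists were not compared directly. More expanding tissue in the COS sample, as in younger leaves, cannot be told apart either. The median of the KEGG cutin and wax set stood at percentile 91.1, inside the band. Yet 8 of its 28 genes were at least 2-fold higher and 0 lower, against 655 higher and 301 lower of all 27451 genes. A median does not register a shift of part of a set, so the percentile does not decide. The cell cycle list stood at 28.4, and between 28.4 and 94.2 under the 10 alternatives. An effect of the agent or of the virus load on growth also stays open and was not tested.

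Genes at least 4-fold apart might be copies of 1 locus that were assembled apart and expressed in 1 library each, as for plants of different genotype. The test of this was written before its result was seen. Of 90 non-viral genes with at least 100 counts and at least 4-fold apart, 55 higher and 35 lower in COS, 8 (8.89%) had a gene of the same assembly component at least 2-fold apart in the other direction. Matched random sets gave a median of 6.67% and reached 13.3% in 100 draws, so this explanation cannot be told apart from chance, and most of the partners carried another annotation. Only partners of the same component were counted, so copies placed in different components would be missed.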
